A study of Mus musculus with 6 samples.

How the data were processed

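RNA from thymus was sequenced in 3 libraries from control and 3 from K5-rtTA:TetO-RANKL mice. Per the labels' protocols, total RNA was taken with TRIzol and a column kit, and stranded mRNA libraries were made from 250 ng. The authors deposited a table of raw counts, whole numbers of reads per gene and library. Per the submitters' processing notes STAR and the mm10 mouse genome were used. The version of STAR, the counting tool, its strand setting and the annotation release are not given in the sources used here, so overlapping, antisense and near-identical genes may share reads. Gene symbols and Entrez identifiers were taken as deposited, and coordinates from a RefSeq gene table of GRCm38, the assembly of mm10.

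The table held 24054 genes, of which 3257 had 0 reads in all libraries. It held no gene segments of immunoglobulins or T cell receptors and no mitochondrially encoded genes. Library totals ran from 18254870 to 25357060 counts, and a floor of 3 reads in a library was 0.118 to 0.164 CPM; floors and counting intervals cover counting error only. The 45S ribosomal RNA precursor took 1.06% to 1.59% of reads per library. All 6 libraries held Xist reads and 0 reads of 4 Y-linked genes. Pairs of libraries within a group differed by far more than sampling noise, with a chi-square per degree of freedom of 33.7 to 72.0, so none was treated as a repeat. Replicates were numbered in accession order and pair nothing across groups. The titles look like animal numbers, but nothing else in the labels says that the libraries came from separate animals, and neither litter nor sex is given, so p-values measure the spread between these samples.

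The comparison was fixed before the data were examined. Genes were kept by edgeR's filterByExpr, scaled by TMM factors and tested with the robust quasi-likelihood fit and test of edgeR 4.0.16 in R 4.3.3, two-sided, with no covariate. Benjamini-Hochberg adjustment ran over the 16096 genes kept, with a threshold of 0.05. CPM values used TMM-scaled totals, and errors of log2 fold changes are standard errors derived from the F statistic. A total of 36 gene lists with 581 genes, 566 of them in the table after matching older symbols, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and adjusted over the 36 lists. camera with an estimated correlation and fry were the alternatives. Of 545 listed genes tested, 22 were on more than 1 list.

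Named genes followed a rule set at the same time. It took Tnfsf11, the 10 largest increases and 10 largest decreases among called genes with a mean log2 CPM of at least 1 and no overlap between groups, up to 4 members of each list with the smallest p, and 15 genes given whatever their outcome. Predicted genes, names ending in Rik, pseudogenes and receptor segments were counted but not named. Members outside the rule are named where 8 or fewer of a list moved one way or were not called, and were chosen after their values were seen. The values of 2 genes within these rules are not reported here.

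The same code was tested on simulated counts in which 200 genes were changed. Of 14776 genes tested there, 42% of those changed 2-fold, 86% of those changed 4-fold and 96% of those changed 8-fold were called, all in the right direction, and 0% of those changed 1.5-fold. Of 119 calls 7 were false. Of 200 lists of unchanged genes 0.5% had p under the threshold, and all of 20 lists of risen genes were called. The simulated genes varied independently, so these list rates do not cover real lists, whose estimated correlation reached 0.681. With only 200 genes changed, the simulation also did not test scaling or recovery where 63.4% of tested genes were called.

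Alternatives were RLE, upper-quartile and no composition factors, 2 other low-count filters, a fit without robust estimation, a block for the range of the title number, each library left out, DESeq2 1.42.0, limma-voom with and without quality weights, a threshold of 0.01 and a test against a 1.5-fold change. Control replicate 2 was the only library in its title-number range, so with that block it added nothing to the estimated group difference. A run without the 45S precursor was added after seeing the data. Thinning drew reads without replacement to the smallest library total. Figures were drawn with matplotlib 3.10.9.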

Results

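Messenger RNA was measured in whole thymus, in 3 libraries from control mice and 3 from mice carrying K5-rtTA and TetO-RANKL, a transgene pair in which doxycycline turns on the cytokine RANKL in cells that use the keratin 5 promoter, such as basal and medullary epithelium. Both groups received doxycycline, and the controls were described as carrying a single transgene. The labels conflict on the schedule, with doxycycline given for 1 week from week 8 of life in one text and for 2 weeks from week 9 in another. The 3 control libraries held 19771112, 18654395 and 21453466 counted reads, and the 3 RANKL libraries 18254870, 25357060 and 20465867. The study asked how induced RANKL changed the mRNA content of the thymus, which makes 1 comparison, RANKL over control.

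Transcripts of the induced gene itself, Tnfsf11, which encodes RANKL (Entrez gene 21943, chromosome 14, 78277446 to 78308043 in GRCm38), rose from 7.08 ± 1.58 to 3512 ± 1221 CPM, counts scaled to library size (mean ± SD, n = 3 per group). That was 495-fold, a log2 fold change of 8.95 ± 0.39 (SE; edgeR adjusted p = 1.62e-06), and the counts do not separate the transgene's transcript from that of the mouse's own gene. Transcripts of medullary epithelium rose with it, among them Aire, the regulator of tissue-restricted genes (chromosome 10, 78030022 to 78043610), from 10.3 ± 2.39 to 149.7 ± 73.8 CPM, or 14.5-fold. Transcripts of double-positive thymocytes, the CD4 and CD8 expressing precursors that fill the cortex, fell, with Rag1, a subunit of the recombinase that assembles T cell receptor genes (chromosome 2, 101638252 to 101649532), going from 2975 ± 856 to 80.1 ± 77.0 CPM. Psmb11, the proteasome subunit of cortical epithelium (chromosome 14, 54625310 to 54629556), fell from 125.0 ± 15.1 to 2.03 ± 2.17 CPM, and genes of keratinocytes, fibroblasts, neutrophils and inflammation rose.

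**Figure D1:**
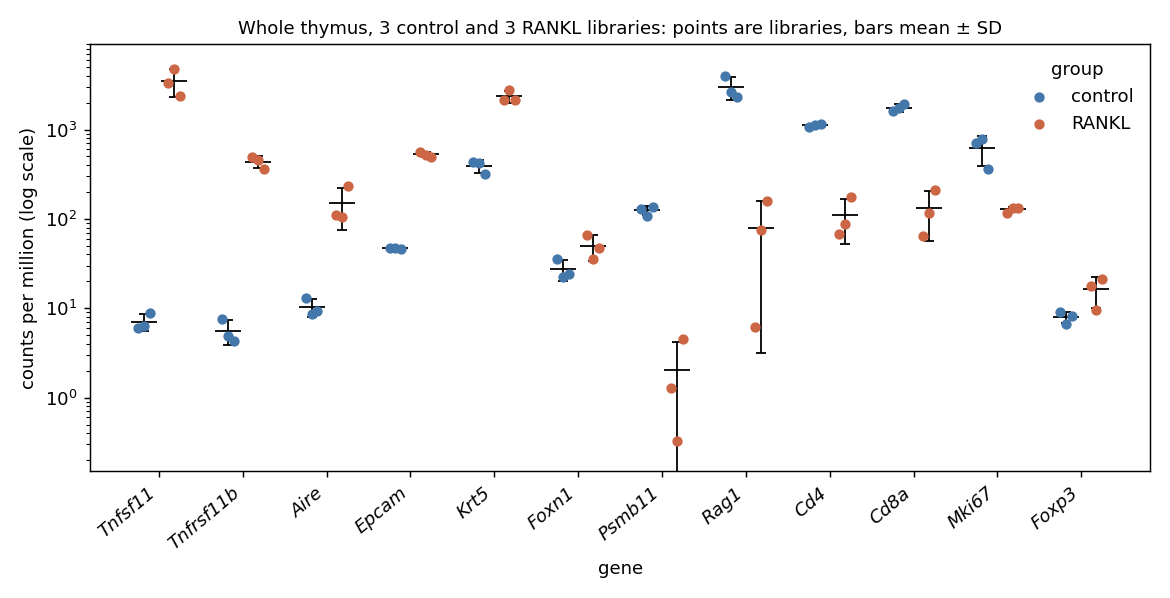
CPM on a log axis for 12 genes in each library, with control libraries in blue, RANKL libraries in orange, and horizontal marks and bars for mean ± SD of 3 libraries (the lower SD bar of Psmb11 in RANKL runs off the axis, since the SD, 2.17, exceeds the mean, 2.03). Tnfsf11, Tnfrsf11b, Aire, Epcam and Krt5 stand higher in every RANKL library than in any control library, and Psmb11, Rag1, Cd4, Cd8a and Mki67 lower.

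Of 16096 genes tested, 5437 were higher and 4765 lower in RANKL at an adjusted p under 0.05, and 5894 were not called. At least 4-fold changes were more often increases, with 2771 genes higher and 552 lower. Under a test against a 1.5-fold change the count of lower genes was 2654. The first principal component of log2 CPM held 88% of the variance and separated the groups, and the second held 4.69%. Across genes, Spearman correlations of CPM were 0.973 to 0.986 between libraries of the same group and 0.799 to 0.854 between groups; genes are not independent replicates.

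The 10 largest increases among genes passing the naming rule were in Cwh43, Cxcl5, Nlrp12, Sprr2g, Arg1, Il19, Sprr2d, Tmprss11g, Krt6b and Chil4. Cxcl5, a chemokine that draws neutrophils, rose by a log2 fold change of 11.10 ± 0.65, and Arg1, arginase 1, rose from 0.898 ± 0.146 to 1015 ± 582 CPM (log2 fold change 10.14 ± 0.52). Krt6b, a keratin of activated epidermis, rose by 9.54 ± 0.52, Tmprss11g by 9.56 ± 0.68, Sprr2g by 10.18 ± 0.88, Sprr2d by 9.88 ± 0.66 and Chil4 by 9.47 ± 0.65. The Sprr2 and chitinase-like genes belong to families of near-identical copies, so their reads may be shared between copies and these values are uncertain. Cwh43 and Nlrp12 had 0 reads in every control library, so Cwh43 was at least 394-fold higher and Nlrp12 at least 223-fold higher against a floor of 3 counts over the control group, bounds that ran from 245 to 512 and from 140 to 296 with 1 library left out. Il19 had 3 control reads, a ratio of 1180 with a 95% counting interval of 405 to 5740. Leaving out RANKL replicate 2 gave the lowest bounds and moved Cxcl5 to 10.47, Sprr2g to 9.20, Sprr2d to 9.27, Tmprss11g to 8.87 and Il19 to 9.01, all still called. Leaving out control replicate 1 moved Sprr2d to 10.70 and Chil4 to 10.16, and leaving out control replicate 2 moved Il19 to 10.78.

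The 10 largest decreases were in Psmb11, Rag1, C2cd4d, Dntt, Ptcra, Arpp21, H2-T3, Cnga1, Themis and Rag2. The log2 fold change was -5.95 for Psmb11, -5.21 for Rag1, -5.21 for C2cd4d, -5.10 for Dntt, which adds nucleotides at receptor junctions, and -5.09 for Ptcra, the pre-T cell receptor alpha chain. It was -4.94 for Arpp21, -4.91 for H2-T3, -4.86 for Cnga1, -4.86 for Themis, a T cell receptor signalling adaptor, and -4.67 for Rag2, the partner of Rag1, with standard errors between 0.517 for Themis and 0.942 for Rag1. C2cd4d had only 1, 2 and 5 reads in RANKL replicates 1, 2 and 3, and Cnga1 1, 5 and 23, so the size of these 2 decreases is uncertain. Among RANKL libraries, replicate 3 held the most of each of the 10 transcripts. Without it the log2 fold changes were -7.31 for Psmb11, -6.15 for Rag1, -5.97 for C2cd4d, -6.47 for Dntt, -6.33 for Ptcra, -6.00 for Arpp21, -5.91 for H2-T3, -6.51 for Cnga1, -5.60 for Themis and -6.02 for Rag2. Without RANKL replicate 1 they were -4.62 for Rag1 and -4.08 for Rag2.

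**Figure D2:**
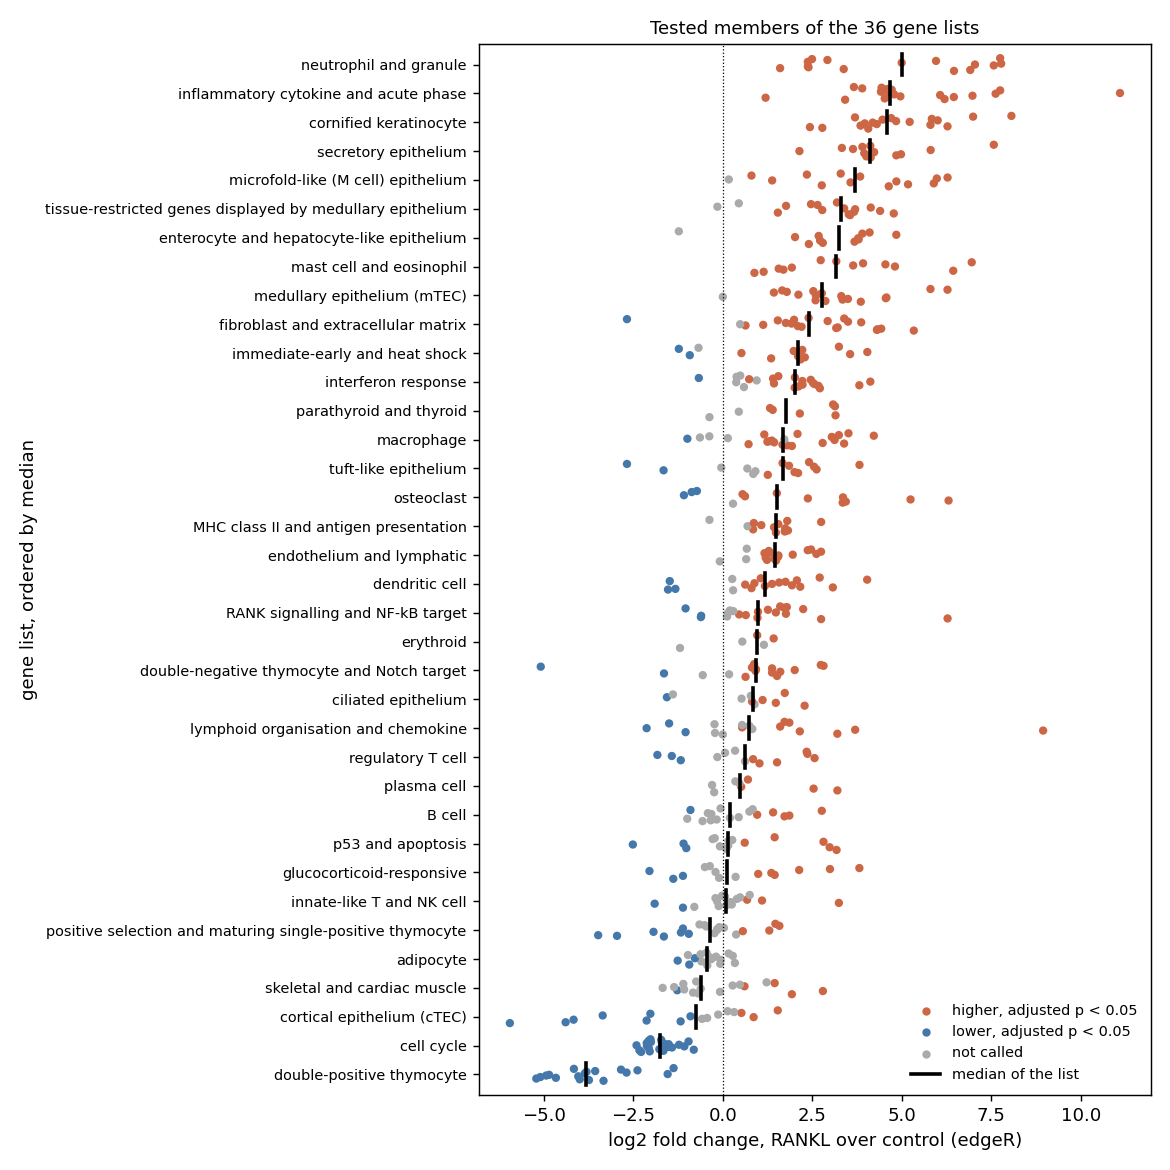
log2 fold change of RANKL over control (x axis) for each tested member of 36 gene lists (y axis), ordered by the list median (black mark); orange and blue points are genes called higher and lower by edgeR, grey points were not called. Medians run from -3.83 for double-positive thymocytes to 4.998 for neutrophil and granule genes.

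Of 36 gene lists fixed before the data were examined, 19 were higher and 3 lower by camera with a preset correlation, and 14 were not called. With an estimated correlation camera called no list in either direction, the smallest adjusted p being 0.0533, and 7 lists had an unadjusted p under 0.05. fry called 27 higher and 3 lower. Other splits of the 6 libraries called from 9 to 27 lists with the preset correlation while calling 0 genes by edgeR (11 to 178 at an unadjusted p under 0.05). Every other split mixed control and RANKL libraries within its groups, so part of the RANKL difference could remain in it. Its list calls are therefore not a rate expected by chance. The list calls did not separate this comparison from other splits, and the member counts carry the description. Adjusted over the list alone, the member counts were the same in 29 lists. The other 7 are given beside their lists.

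Medullary epithelium rose in 18 of 19 tested genes, with a median log2 fold change of 2.77 (adjusted p = 7.97e-12; adjusted p = 0.0533 with an estimated correlation). Epcam, an epithelial adhesion molecule, rose from 46.7 ± 1.03 to 527 ± 35.8 CPM, Krt5 from 392 ± 63.1 to 2360 ± 375 and Krt14, its basal keratin partner, from 97.9 ± 10.9 to 996 ± 297. The tight junction gene Cldn4 rose by 4.57 ± 0.25 on the log2 scale, the costimulatory ligand Cd80 by 3.31 ± 0.23 and Fezf2, a second regulator of tissue-restricted genes, by 2.87 ± 0.29. Ccl19 was the member not called, at -0.00. Tissue-restricted genes that medullary epithelium displays rose in 14 of 16, with a median of 3.29 (adjusted p = 0.00101; adjusted p = 0.437 with an estimated correlation). Csn2, a milk casein, rose 27.4-fold, Gad1, a neuronal glutamate decarboxylase, 17.5-fold, Tff3, a mucosal trefoil peptide, 12.7-fold and Fabp9, a testis fatty acid binding protein, 10.5-fold. Maoa and Tg were not called, at -0.15 and 0.45.

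Lists of specialised epithelium moved to different extents. Microfold-like genes rose in 13 of 14, with a median of 3.70 (adjusted p = 1.94e-12; adjusted p = 0.11 with an estimated correlation), including Gp2, a bacterial uptake receptor, 24.9-fold, the chemokine Ccl9, 59.6-fold, Tnfaip2, 11.9-fold and Tnfrsf11b, the decoy receptor for RANKL, 77.8-fold. Anxa5 was not called, at 0.17. Cornified keratinocyte genes rose in 18 of 18, with a median of 4.59 (adjusted p = 4.82e-11; adjusted p = 0.234 with an estimated correlation). Sprr1a, a cornified envelope precursor, rose by 6.99 ± 0.53, or by 6.31 without RANKL replicate 2, the protease inhibitor Spink5 by 5.80 ± 0.47, Calm4 by 4.71 ± 0.28 and Krtdap by 4.30 ± 0.34. Secretory epithelium rose in 13 of 13, with a median of 4.12 (adjusted p = 1.87e-07; adjusted p = 0.175 with an estimated correlation), including the mucins Muc1, 16.1-fold, and Muc13, 28.8-fold. Enterocyte and hepatocyte-like genes rose in 11 of 12, with a median of 3.24, or 3.87 without control replicate 1 (adjusted p = 0.000734; adjusted p = 0.408 with an estimated correlation), among them Vil1, the microvillus protein villin, 12.8-fold and the apolipoproteins Apoa1, 13.9-fold, and Apoa4, 13.8-fold. Lgals4 was not called, at -1.23. Tuft-like epithelium was not called as a list (adjusted p = 0.0507), with 9 members higher, 2 lower and 4 not called of 15, and 11 higher and 2 lower adjusted over the list alone. Alox5, Ptgs1 and Ltc4s, enzymes of leukotriene and prostaglandin synthesis, rose by 2.55 ± 0.29, 1.85 ± 0.20 and 2.41 ± 0.28, while Plcb2 and Il17rb fell. Adjusted over all genes, Trpm5, Gnb3, Bmx and Rgs13 were not called, at 0.85, 0.91, 0.68 and -0.04. The tuft-like list passed the threshold without control replicate 1 (0.0449) or RANKL replicate 2 (0.0396), with RLE factors (0.0489), library totals (0.0493) or either other filter (0.0414 and 0.0479), and without the 45S precursor (0.0494). Ciliated epithelium was not called (adjusted p = 0.585), with 5 higher, 1 lower and 4 not called of 10. Foxj1, a regulator of ciliogenesis, rose by 2.29 ± 0.56, or by 3.26 without control replicate 1, and Dnah9, a ciliary dynein, fell by 1.56.

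Cortical epithelium split, with 8 genes lower, 3 higher and 5 not called of 16, and a median of -0.74 (adjusted p = 0.0207; adjusted p = 0.368 with an estimated correlation). Besides Psmb11, the genes that fell were Prss16, Ccl25, Tbata, Cxcl12, Enpep, Ly75 and Ctsl. Cxcl12, a chemokine that guides early thymocytes, fell from 259 ± 31.9 to 59.1 ± 4.73 CPM, and Enpep, glutamyl aminopeptidase, fell by 2.03 on the log2 scale. Krt8 rose by 0.52 ± 0.20. Foxn1, the master transcription factor of thymic epithelium, went from 27.5 ± 7.14 to 49.9 ± 15.8 CPM, a log2 fold change of 0.86 ± 0.26 (adjusted p = 0.0166). Its call was lost without control replicate 2 (0.0769) or control replicate 3 (0.0664).

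Double-positive thymocyte genes fell in 18 of 18, with a median of -3.83, or -4.47 without RANKL replicate 3 (adjusted p = 7.77e-10; adjusted p = 0.336 with an estimated correlation). Cd4 went from 1120 ± 37.6 to 111 ± 58.2 CPM and Cd8a from 1759 ± 175 to 131 ± 74.1 CPM, 10.1-fold and 13.4-fold lower. Tcf7, a T lineage transcription factor, was 14.5-fold lower. Cell cycle genes fell in 24 of 24, with a median of -1.75 (adjusted p = 2.72e-14; adjusted p = 0.207 with an estimated correlation). Mki67, a marker of dividing cells, went from 622 ± 232 to 128 ± 8.56 CPM, and log2 fold changes were -2.41 for Kif11, a spindle motor, -2.33 for Ccnb2, a mitotic cyclin, -2.12 for Ccna2 and -2.07 for Pcna, the replication clamp. Double-negative thymocyte and Notch target genes rose in 12 of 16, with 2 lower and 2 not called and a median of 0.92 (adjusted p = 0.0391; adjusted p = 0.451 with an estimated correlation). Cd44, an adhesion receptor also made by myeloid and stromal cells, rose by 2.81 ± 0.21, Mpzl2 by 2.74 ± 0.26, Spi1, a myeloid and early thymocyte transcription factor, by 2.01 ± 0.20 and Il2ra, the interleukin 2 receptor alpha chain, by 1.51 ± 0.17, while Dtx1 and Ptcra fell. The list lost its call without RANKL replicate 2 (0.0711), RANKL replicate 3 (0.0934) or control replicate 3 (0.0732), and with a block for the range of the number in each sample's title (0.0504).

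Genes of positive selection and maturing single-positive thymocytes were not called as a list (adjusted p = 0.101), with 4 higher, 7 lower and 9 not called of 20. Itm2a, Cd5, a negative regulator of T cell receptor signalling, and Gata3, a CD4 lineage factor, fell to log2 fold changes of -3.48, -2.96 and -1.94, while H2-K1, an MHC class I heavy chain, rose by 1.58 ± 0.22. The list passed the threshold without control replicate 2 (0.0425) or RANKL replicate 3 (0.00889), with no filter (0.0376) and with the block for the title number (0.0311). Regulatory T cell genes were not called (adjusted p = 0.204), with 6 higher, 3 lower and 4 not called of 13. Tnfrsf9, Capg and Lrrc32 rose by 2.56 ± 0.22, 2.36 ± 0.16 and 2.34 ± 0.25. Ikzf2, Gpr83 and Folr4 fell, with log2 fold changes of -1.18, -1.43 and -1.83. Foxp3, the lineage factor, went from 7.98 ± 1.14 to 16.2 ± 6.04 CPM (log2 fold change 1.02 ± 0.31, adjusted p = 0.0155), and its call was lost without control replicate 2 (0.0653), without RANKL replicate 3 (0.0574) and with the block for the title number (0.0646). Innate-like T and NK cell genes were not called (adjusted p = 0.978), with 3 higher, 2 lower and 12 not called of 17, and 2 higher and 1 lower adjusted over the list alone. Gzmb, a granzyme of cytotoxic cells, rose by 3.24 ± 0.29 and Gzma fell (-1.91, or -2.58 without RANKL replicate 3).

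B cell genes were not called (adjusted p = 0.78), with 5 higher, 1 lower and 11 not called of 17. Spib, which medullary and microfold-like epithelium also use, rose by 2.77 ± 0.37, Fcer2a, the low-affinity IgE receptor, by 1.86 ± 0.35 and the complement receptor Cr2 by 1.72 ± 0.45. Without RANKL replicate 3 the list's direction turned to lower (0.749). Plasma cell genes were not called (adjusted p = 0.199), with 4 higher and 4 not called of 8, led by Sdc1, a syndecan that epithelium also makes, 3.20 ± 0.26, and Prdm1, 2.54 ± 0.25. Lymphoid organisation and chemokine genes, a list that holds Tnfsf11 itself, were not called (adjusted p = 0.192), with 8 higher, 3 lower and 6 not called of 17. Cxcl13, a B cell attracting chemokine, rose 9.19-fold, and Bcl6 was 2.83-fold lower; without RANKL replicate 2 the list passed the threshold (0.0165).

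RANK signalling and NF-kB target genes rose in 13 of 20, with 3 lower and 4 not called and a median of 0.97 (adjusted p = 0.00164; adjusted p = 0.432 with an estimated correlation). Tnfrsf11a, the receptor of RANKL, rose from 10.8 ± 4.43 to 72.7 ± 25.3 CPM, and Bcl3, Nfkb2 and Ltbr, of the NF-kB pathway, rose by 2.25 ± 0.17, 1.76 ± 0.20 and 1.71 ± 0.17. Traf2, Traf6 and Ltb fell. Osteoclast genes rose in 9 of 13, with 3 lower and 1 not called and a median of 1.51 (adjusted p = 0.00845; adjusted p = 0.207 with an estimated correlation). Dcstamp and Ocstamp, which osteoclast fusion requires, rose by 5.25 ± 0.29 and 6.31 ± 0.53, Ocstamp by 6.99 without control replicate 1, Ctsk, a bone-degrading protease, by 3.35 ± 0.25 and Atp6v0d2 by 3.36 ± 0.28. Nfatc1, Ostm1 and Car2 fell, and Acp5 was not called, at 0.28.

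Neutrophil and granule genes rose in 15 of 15, with a median of 4.998, the highest of any list with all libraries and 4.37 without RANKL replicate 2, where cornified keratinocyte and inflammatory genes stood higher, and 4.595 without control replicate 3, where inflammatory genes did, at 4.90 (adjusted p = 7.03e-09; adjusted p = 0.207 with an estimated correlation). Lcn2, an iron-sequestering protein that epithelium also makes, rose by 7.75 ± 0.42, Retnlg by 7.05 ± 0.44, S100a9, from the calprotectin pair, by 6.92 ± 0.50 and the chemokine receptor Cxcr2 by 7.78 ± 0.58, or by 7.15 without RANKL replicate 2. Inflammatory cytokine and acute phase genes rose in 20 of 20, with a median of 4.67 (adjusted p = 9.45e-13; adjusted p = 0.207 with an estimated correlation), including Cxcl1, a neutrophil chemoattractant, 27.6-fold and Il1rn, the interleukin 1 receptor antagonist, 87.8-fold. Macrophage genes rose in 17 of 22, 18 adjusted over the list alone, with 1 lower and a median of 1.69 (adjusted p = 2.37e-06; adjusted p = 0.224 with an estimated correlation), among them Gpnmb, 18.6-fold, Lgals3, galectin 3, 11.4-fold and Fcgr1, an IgG receptor, 8.70-fold. Dendritic cell genes rose in 14 of 19, with 3 lower and 2 not called and a median of 1.18 (adjusted p = 0.00326; adjusted p = 0.339 with an estimated correlation). Ccl17 and Itgax rose 16.4-fold and 8.42-fold, whereas Xcr1, Clec9a and Cd83 fell. Mast cell and eosinophil genes rose in 13 of 13, with a median of 3.17 (adjusted p = 0.000144; adjusted p = 0.336 with an estimated correlation). Hdc, which makes histamine, rose by 3.64 ± 0.42 and the eosinophil peroxidase Epx by 4.54 ± 0.54, with Hdc at 4.23 without control replicate 1.

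MHC class II and antigen presentation genes rose in 11 of 13, 12 adjusted over the list alone, with a median of 1.48 (adjusted p = 0.00288; adjusted p = 0.451 with an estimated correlation), including Ctss, a protease that trims the invariant chain, 6.71-fold and H2-Eb1, 3.53-fold. Interferon response genes rose in 16 of 22, 17 adjusted over the list alone, with 1 lower and a median of 2.01 (adjusted p = 7.83e-07; adjusted p = 0.432 with an estimated correlation). Rsad2, an antiviral enzyme, rose 17.4-fold, Isg15, a ubiquitin-like modifier, 6.55-fold and Oas1a 6.37-fold. Immediate-early and heat shock genes, which tissue handling can also raise, rose in 10 of 13, with 2 lower and a median of 2.10 (adjusted p = 0.00259; adjusted p = 0.408 with an estimated correlation), among them Atf3, 11.8-fold, and Ier3, 16.4-fold. Glucocorticoid-responsive genes were not called (adjusted p = 0.264), with 6 higher, 3 lower and 5 not called of 14. The metallothioneins Mt1 and Mt2 rose by 2.99 ± 0.22 and 3.82 ± 0.22 and Sesn1 fell by 2.05 on the log2 scale. p53 and apoptosis genes were not called (adjusted p = 0.525), with 5 higher, 3 lower and 7 not called of 15. Cdkn1a, a cell cycle inhibitor, rose by 3.18 ± 0.20 and Pmaip1, a pro-apoptotic BH3 protein, by 2.98 ± 0.16, whereas Trp53inp1 fell by 2.52.

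Fibroblast and extracellular matrix genes rose in 19 of 21, with a median of 2.40 (adjusted p = 1.93e-08; adjusted p = 0.224 with an estimated correlation). The fibrillar collagens Col1a1, Col1a2 and Col3a1 rose by 5.34 ± 0.41, 4.31 ± 0.32 and 4.32 ± 0.33 on the log2 scale. Thy1, which thymocytes also make, was lower and Dpt was not called. Endothelium and lymphatic genes rose in 15 of 18, with 3 not called and a median of 1.46 (adjusted p = 0.00326; adjusted p = 0.432 with an estimated correlation), including the lymphatic genes Lyve1, 6.70-fold, and Flt4, 5.17-fold, and Plvap, 2.90-fold.

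Lists of tissue that can be dissected with the thymus were not called by camera. By fry, the parathyroid and thyroid list (adjusted p = 0.00553) and the erythroid list (adjusted p = 0.0268) were higher. Adipocyte genes (adjusted p = 0.192) had 3 lower and 14 not called of 17. Plin1, which coats lipid droplets, Cfd and Cidea fell, with log2 fold changes of -0.94, -0.78 and -1.26. Cidea lost its call without control replicate 3 (0.0746) or RANKL replicate 3 (0.0602), and the list passed the threshold without control replicate 2 (0.0456). Muscle genes (adjusted p = 0.978) had 4 higher, 1 lower and 12 not called of 17, 1 higher adjusted over the list alone, with a median of -0.62, or 0.73 without control replicate 1 and 0.94 with the block for the title number, and a mean of -0.04, although the test's direction was higher; that direction turned with upper-quartile factors, library totals, a CPM filter of at least 1, the run without the 45S precursor, and without control replicate 3, RANKL replicate 1 or RANKL replicate 2. Chrna1, a muscle acetylcholine receptor subunit, rose by 2.80 ± 0.48. Erythroid genes (adjusted p = 0.602) had 2 higher and 3 not called of 5, 1 higher adjusted over the list alone. Tfrc, the transferrin receptor, rose by 0.96 ± 0.15. The adult globin genes were listed at 0 in all libraries, as were Ccl21a, Ccl21b and Ccl21c, all of which have near-identical copies. Parathyroid and thyroid genes (adjusted p = 0.151) had 6 higher and 2 not called of 8. The calcium receptor Casr rose 8.87-fold, Calca, the calcitonin gene, 8.77-fold, Chga 4.44-fold and Iyd 8.46-fold. Pth and Tg were the members not called, at log2 fold changes of -0.37 and 0.45. Tg was also on the list of tissue-restricted genes that medullary epithelium displays. Which cells made the parathyroid and thyroid transcripts was not tested.

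More genes were detected in RANKL libraries at equal depth. When every library was thinned to 18254870 reads, 14738 ± 260 genes had at least 10 reads in control and 16186 ± 323 in RANKL (SD, n = 3 per group; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). The lowest RANKL library had 15814 such genes and the highest control library 14896.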

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

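The run without the 45S precursor was chosen after seeing the data; the other alternatives were planned, and that of leaving out receptor segments and mitochondrial genes was not run because the table holds none. No gene called in the comparison had the opposite sign in any of 17 settings in which it was tested, and Tnfsf11 stayed called. Of 2786 refits of named genes, 2738 kept their direction and side of the threshold, 41 lost the call, 7 gained one and 0 reversed. Upper-quartile factors shifted genes by a median of 0.104 (log2) and made 58.3% of calls increases, against 53.3%. Lower genes numbered 2654 in the test against a 1.5-fold change, which asks for more, and 3902 to 4624 with 1 library left out. With an estimated correlation 0 lists were higher and 0 lower; the estimates ran from -0.0505 to 0.681, and the cause was not tested. Lower lists numbered 3 to 5 with 1 library left out, 5 without control replicate 2. Lists that reversed were uncalled throughout, and the cause was not tested. The muscle list reversed with upper-quartile factors (adjusted p = 0.915), library totals (0.998), a CPM of at least 1 (0.927) and without the 45S precursor (0.997). It also reversed without control replicate 3 (0.54), RANKL replicate 1 (0.645) or RANKL replicate 2 (0.914), and ranged from 0.436 to 0.914 with 1 library left out. The innate-like T and NK list reversed with upper-quartile factors (0.964), library totals (0.998) and no filter (0.962). It also reversed without control replicate 1 (0.788), RANKL replicate 1 (0.895) or RANKL replicate 3 (0.557), and ranged from 0.557 to 0.98 with 1 library left out. The B cell list reversed without RANKL replicate 3 (0.749), in a range of 0.262 to 0.866. Depth limits the genes with few control reads, such as Cwh43, Nlrp12 and Il19, and those with few RANKL reads, such as C2cd4d and Cnga1.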

Other observations

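The genes in this paragraph and the next were chosen after their values were seen, and all tests of explanations below were written, and those of neutrophil and cortical genes later revised, after the results were seen. Chil3, a chitinase-like lectin with a near-identical copy, rose by 8.60 ± 0.61 on the log2 scale, Retnla by 3.05 ± 0.36, Mrc1, the mannose receptor, by 3.39 ± 0.50 and Il13 from 3.81 ± 1.57 to 35.1 ± 9.64 CPM. Il4 rose by 1.70 ± 0.47 (adjusted p = 0.0106) and lost its call without RANKL replicate 3 (0.0536) and with the block for the title number (0.0669). Mrc1 was at 2.55 without RANKL replicate 2, and Chil3 at 9.27 without control replicate 1. Spp1, osteopontin, rose from 4.01 ± 1.07 to 1997 ± 1052 CPM, and the matrix metalloproteinase Mmp12 from 4.55 ± 1.41 to 755 ± 151.

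Grouping tested genes by the letters that open their symbols gave 201 families of at least 10 genes. Keratins rose in 47 of 48, kallikreins in 21 of 21, Serpinb serine protease inhibitors in 19 of 19 and matrix metalloproteinases in 17 of 19. All 10 genes with the Mcm prefix fell, Mcm3ap and the minichromosome maintenance genes, and zinc finger genes with the Zfp prefix fell in 203 of 329 and rose in 33. Adjusted p ranged from 6.07e-16 for keratins to 2.02e-05 for the Mcm prefix with the preset correlation, and from 0.504 to 0.558 for these 6 families with an estimated one.

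With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. Each split other than the real one also mixed control and RANKL libraries within its groups. Such mixing widens the spread within groups and can keep part of the difference between them, so these counts are not a rate expected by chance. The real split called 5437 genes higher and 4765 lower, and the highest other split called 0 (178 at an unadjusted p under 0.05), so 1 of 10 splits gave as many in each direction. For lists the real split gave 19 higher and 3 lower and the highest other 24 in one direction; 4 splits gave as many as 19 and 10 as many as 3.

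Lists of other cell types moved by different amounts. If a lower share of thymocytes had raised every other cell type alike, 19 such lists would share a median, but the highest and lowest medians, 4.998 for neutrophils and -0.62 for muscle, lay 5.62 apart on the log2 scale (4.74 to 6.09 with 1 library left out; the muscle median was 0.73 without control replicate 1) against a spread of 1.48 within lists. Membership of the 280 genes on 1 of these lists was permuted for a Kruskal-Wallis rank statistic over the lists, not for this gap. That permutation test gave p = 1e-05, the smallest that 100000 permutations can give, although genes are not independent. The 19 lists were chosen after their medians were seen. A lower thymocyte share may still account for part of each rise, and changes within the cell types that rose stay open.

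Neutrophil and granule genes rose by a median of 4.998 (4.37 without RANKL replicate 2). More residual blood would raise erythroid genes by about as much, and the highest upper 95% bound among the 5 tested members of the erythroid list was 2.93, that of Slc4a1, which was at 2.51 (adjusted p = 0.0333) with the block for the title number. The embryonic globins Hbb-y, Hba-x and Hbb-bh1 rose by 4.31, 3.43 and 3.15 (Hbb-bh1 by 3.78 without control replicate 1), Hbb-y with an upper bound of 5.54, and the adult globins could not be used, so residual blood stays open. Expression by epithelium of the granule genes that it also makes would leave the other 9 tested members behind, but 7 of the 9 had a lower bound above 1 (6 without control replicate 3 or RANKL replicate 2), the exceptions being Elane at 0.29 and Ngp at 0.73. Epithelium may still account for part of the rise of the genes it makes, such as Lcn2 and Ltf, and entry of neutrophils was not tested.

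Cortical epithelium genes moved apart. A lower share of thymocytes would have raised them all, but 9 of 16 members had an upper 95% bound below 0 (8 without RANKL replicate 1 or RANKL replicate 3). Fewer cortical epithelial cells would lower all 16, and the 9 with such a bound, 8 of them called lower and Dll4 not (adjusted p = 0.0587), leave this undecided, since Psmb11, Prss16 and Ccl25 fell by 4.17 or more on the log2 scale, Ly75 by 1.18 and Ctsl by 0.91, and 3 members rose. Other cells also make several members, and the list does not separate them. Fewer cells and lower expression in each cell cannot be told apart.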
